A study of Rattus norvegicus with 9 samples.

How the data were processed

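RNA-seq was performed on NRK-49F cells, an established line of rat kidney interstitial fibroblasts. All 9 libraries came from cells given TGF-β1, a cytokine that drives fibroblasts towards the matrix-producing, contractile myofibroblast state. Per the labels, 3 libraries came from cells given TGF-β1 with vehicle, 3 from cells given TGF-β1 with the compound YEXX-2A and 3 from cells given TGF-β1 with the compound YWCH-4A. The labels give a TGF-β1 incubation of 48 h and no dose or timing of either compound. The compounds are known here by their code names alone, and cells without TGF-β1 were not analysed here. Per the labels, the series has 3 biological replicates per condition. Nothing states whether the replicates were separate cultures set up on separate days, so p-values measure the spread between these libraries.

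Per the labels' protocols, mRNA was enriched from total RNA with oligo(dT) beads, fragmented, and made into libraries with an NEBNext Ultra RNA kit. Reads of a gene and of an overlapping antisense gene are treated here as not separable. Per the submitters' processing notes, StringTie 1.3.1, RSEM, DESeq2 and edgeR were used, with no role or order given. The aligner, genome build and annotation were not given in the sources used here, and no coordinates are reported. The deposited gene table held an estimated (expected) count and an FPKM value per gene and library, per the file headers. It covered 22050 genes with Ensembl gene identifiers, symbols and pathway terms. Of the deposited estimated counts above 0, 8.87% were not whole numbers, as an estimator that shares reads between gene models gives. A second deposited table held estimated counts and FPKM per group. These differed from the mean of the 3 library values by at most 0.00033, and the table was not used further.

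Estimated counts were rounded to whole numbers. Total counts per library ran from 13675880 to 21923706, which sets the counting error of low genes. Genes with too few counts were removed with filterByExpr of edgeR 4.0.16 (minimum count 10), which left 11473 genes. Another 7019 genes of the table had no count in any library. Libraries were scaled with TMM factors, and CPM values are on the scaled library sizes. Each comparison was tested with the robust quasi-likelihood test of edgeR on all 9 libraries, with group as the single factor. The 3 groups thus shared an estimate of the spread, although the biological coefficient of variation was 16.7%, 7.4% and 3.7% among vehicle, YEXX-2A and YWCH-4A libraries. P-values against vehicle may therefore be too small, and those between the compounds too large. P-values were two-sided and adjusted with the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. Standard errors of log2 fold changes were taken as the change divided by the square root of its F statistic. Symbols shared by 2 or more genes numbered 133, and members of families with near-identical copies (tubulins, Mx, guanylate-binding proteins, ribosomal proteins, RT1 genes) are uncertain because reads can be split between copies.

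Before the data were examined, 37 gene lists with 990 entries, a panel of fibrosis genes, the tests, most alternatives and the rule for naming genes were fixed. Of the list entries, 964 matched a gene of the table, 7 of them through a synonym in the RefSeq gene table of assembly GRCr8. Lists with at least 5 tested genes, 36 in all, were tested with camera of limma 3.58.1 on voom values with a preset correlation of 0.01, and again with an estimated correlation and with fry. The macrophage and leukocyte list had fewer tested genes. The naming rule took the panel, the 6 largest rises and 6 largest falls per comparison among called genes with a mean of at least 1 CPM and no overlap between groups, and the members of a described list with the smallest p-values. Some results on single genes of the panel and lists are not reported here. Named genes with 3 or fewer counts in a group are given with pooled counts and an exact 95% interval of the ratio, which covers counting error only. A gene with no count in a group is given a ratio against 3 assumed counts, without an interval.

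Alternatives were DESeq2 size factors, upper-quartile factors, no filter and a stricter filter (at least 1 CPM in 6 libraries), DESeq2 1.42.0, limma-voom, limma-trend on log2(FPKM + 1), only the 2 groups compared, a replicate block, a minimum 2-fold change, and each library left out. Added after seeing the data were a score of each library on the main axis of within-group variation as a covariate, and counts thinned to a common total of 13675868 per library. The axis was the first component of the deviations of log2 CPM from the group means. All computations ran in R 4.3.3. The edgeR test was also checked on simulated counts with 200 changed genes. Each gene was drawn independently, with a common mean profile and the same spread in every group. The real groups differed in spread, so the shares that follow may not hold for the data. For YEXX-2A against vehicle (11390 genes) it called 58.2% of genes changed 1.5-fold, 81.8% of those changed 2-fold and 96.9% of those changed 4-fold, and 7.9% of its calls were unchanged genes. For YWCH-4A against vehicle (11384 genes) it called 58.2% at 1.5-fold, 85.1% at 2-fold and 98.5% at 4-fold. For YWCH-4A against YEXX-2A (11391 genes) these shares were 62.7%, 88.1% and 98.5%.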

Results

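The series compared rat renal fibroblasts of the NRK-49F line kept in TGF-β1 with vehicle, with YEXX-2A or with YWCH-4A, with 3 libraries per group. Total counts were 15813023, 14062768 and 14321352 in vehicle replicates 1 to 3, 21923706, 19595909 and 13675880 in the YEXX-2A replicates and 20014139, 18062110 and 15145100 in the YWCH-4A replicates. The first principal component held 43.6% of the variance and set the YWCH-4A libraries (39.2 to 40.4) apart from all others (-21.8 to -18.3). The second held 30.4% and ran from the YEXX-2A libraries (-31.9 to -14.7) to vehicle replicate 2 (54.1), with vehicle replicates 1 and 3 at 10.5 and 6.9. The biological coefficient of variation was 16.7% among vehicle libraries, 7.4% among YEXX-2A libraries and 3.7% among YWCH-4A libraries. It was 4.7% among vehicle libraries without replicate 2. A score of each library on the main axis of within-group variation, defined after the data were seen, was 51.3 for vehicle replicate 2 and between -25.8 and 6.0 for the other libraries, with the YEXX-2A libraries at -18.3, -25.8 and -5.6.

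**Figure D1:**
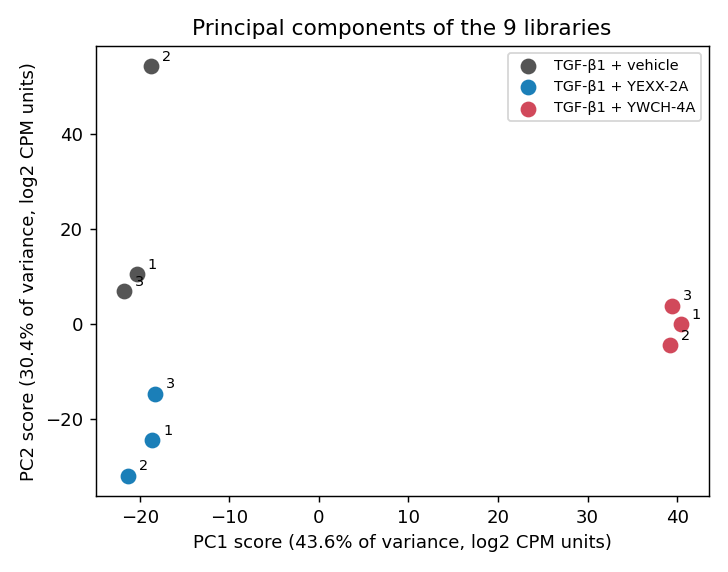
Principal component scores of the 9 libraries from log2 CPM of the tested genes; each point is a library, coloured by group and marked with its replicate number. The YWCH-4A libraries separate on the first axis (43.6% of variance), and vehicle replicate 2 lies at 54.1 on the second (30.4%).

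The first comparison asked which transcripts differed in TGF-β1-treated fibroblasts given YEXX-2A, in a series on small molecules against kidney fibrosis, per its title. Tagln and Acta2, genes of the contractile myofibroblast apparatus, fell. Tagln, an actin-binding protein of smooth muscle, went from 53.7 ± 3.96 to 15.4 ± 0.999 CPM (SD, n = 3 each; log2 fold change -1.80, SE 0.12, edgeR adjusted p = 5.09e-05). Acta2, which encodes α-smooth muscle actin, went from 321.7 ± 52.6 to 125.5 ± 1.16 CPM (log2 fold change -1.36, SE 0.10, edgeR adjusted p = 5.09e-05). Col3a1, a fibrillar collagen, fell by 0.90 on the log2 scale and Col1a1 by 0.55. The small matrix proteoglycan Fmod fell by 1.88. In all, 4145 of 11473 genes were called, 2022 higher and 2123 lower, and 285 of them changed at least 2-fold.

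Among other panel genes, Tgfbr1 rose by 0.91 and Hmox1 fell by 0.46 on the log2 scale. Smaller falls were called for Tgfb1 (-0.37), Ccn2 (-0.25) and Smad3 (-0.23). These calls were lost without YEXX-2A replicate 1 (adjusted p = 0.0615, 0.0941 and 0.0839 in turn) and without replicate 2 (0.0753, 0.104 and 0.119), and those of Ccn2 and Smad3 also with the library score as a covariate. Col1a2 was split over a pair of gene models, whose sum went from 30691 ± 4706 to 20982 ± 1250 CPM (log2 fold change -0.55, SE 0.10, adjusted p = 0.00643), and neither model alone was called with the library score as a covariate. Not called were Fn1 (-0.17), Postn (0.41), Lox (0.09), Timp1 (0.07), Mmp2 (-0.21), Smad7 (0.12), Tgfbr2 (-0.01), Il6 (0.21) and Ccl2 (0.13). With the library score as a covariate Lox was at -0.24 (adjusted p = 0.00421) and Ccl2 at -0.22 (adjusted p = 0.000595). Of 26 tested TGF-β/SMAD targets, 4 rose and 10 fell (6 and 13 adjusted over the list alone), and camera did not call the list (adjusted p = 0.169).

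With YEXX-2A, 19 of 36 collagens and matrix glycoproteins fell and 2 rose (21 and 3 adjusted over the list alone), with Col7a1 at -1.80 and Col5a3 at -1.03. Of 26 genes that modify and crosslink collagen, 19 fell and none rose (19 and 0 adjusted over the list alone), among them the crosslinking enzymes Loxl1 (-0.68) and Loxl2 (-0.42) and the prolyl hydroxylase P4ha3 (-0.45). Camera called both lists (adjusted p = 1.84e-06 for each), and both had an adjusted p = 0.303 with an estimated correlation. Of 23 contractile genes, 12 fell and 3 rose (12 and 3 adjusted over the list alone; camera adjusted p = 0.011, adjusted p = 0.231 with an estimated correlation). Tubulins fell in 9 of 9 cases (9 adjusted over the list alone), led by Tubb2a (-0.79), with a camera adjusted p = 4.8e-05 and an adjusted p = 0.312 with an estimated correlation. Reads can be split between tubulin copies. The medians of these 4 lists were -0.32, -0.39, -0.29 and -0.34 in turn, and -0.29, -0.22, -0.13 and -0.17 with the library score as a covariate, where camera still called each. Without vehicle replicate 2 the contractile and tubulin medians were -0.19 and -0.22. Of 21 matrix proteases and inhibitors, 9 fell and 2 rose (9 and 2 adjusted over the list alone; camera adjusted p = 0.0282, adjusted p = 0.229 with an estimated correlation), and camera did not call this list without vehicle replicate 3 (adjusted p = 0.0508) or with the score (adjusted p = 0.087).

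Interferon-stimulated genes rose in 23 of 34 cases under YEXX-2A and fell in 1 (24 and 1 adjusted over the list alone). The antiviral GTPases Mx2 and Mx1 rose by 1.67 and 1.45 on the log2 scale, Ifit1 by 1.68 and Oasl2 by 0.86. Camera called the list (adjusted p = 7.66e-09), with an adjusted p = 0.0739 with an estimated correlation. Cholesterol synthesis genes rose in 14 of 26 cases and fell in none (15 and 0 adjusted over the list alone). Idi1 rose by 1.41 and Cyp51, the lanosterol demethylase, by 0.95. Camera gave an adjusted p = 0.000229 for this list, and an adjusted p = 0.0739 with an estimated correlation. The median changes of these lists were 0.55 and 0.32, and 0.52 and 0.31 with the library score as a covariate.

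Glycolysis and hypoxia genes fell in 19 of 30 cases and rose in 1 (21 and 2 adjusted over the list alone), with Pgk1 at -0.58, Ldha at -0.46, Pkm at -0.72 and the carbonic anhydrase Ca9 at -0.78 (camera adjusted p = 2.77e-07, adjusted p = 0.0924 with an estimated correlation). Targets of ATF4, the transcription factor of the integrated stress response, fell in 21 of 32 cases and rose in 2 (23 and 3 adjusted over the list alone). Pycr1, an enzyme of proline synthesis, was at -0.68 and Stc2 at -0.63. Camera called the ATF4 list (adjusted p = 6.04e-06), with an adjusted p = 0.312 with an estimated correlation. Cytokine and NF-κB feedback genes fell in 14 of 33 cases and rose in 1 (15 and 1 adjusted over the list alone), among them Nos2 (-0.81) and Cxcl1 (-0.58), with a camera adjusted p = 0.011 and an adjusted p = 0.136 with an estimated correlation. The medians of the glycolysis and hypoxia, ATF4 and cytokine lists were -0.39, -0.33 and -0.33, and -0.32, -0.17 and -0.24 with the library score as a covariate.

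Transcripts that read on RNA quality also moved. Mitochondrially encoded genes rose in 8 of 13 cases (10 adjusted over the list alone; median 0.60, camera adjusted p = 0.000197, adjusted p = 0.337 with an estimated correlation), and ribosomal protein genes in 22 of 46, with 2 lower (22 and 2 adjusted over the list alone; median 0.25, camera adjusted p = 0.000111, adjusted p = 0.313 with an estimated correlation). With the library score as a covariate the medians were 0.27 and 0.16. The G2/M list rose in 13 of 36 cases and fell in 2 (17 and 4 adjusted over the list alone; median 0.26, camera adjusted p = 0.0149, adjusted p = 0.436 with an estimated correlation). Its median was 0.05 with that score, where camera no longer called it (adjusted p = 0.104). Ncapg, a condensin subunit, was at 1.15 and Top2a at 0.85.

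Of the other largest rises with YEXX-2A, Rbp4, a retinol carrier, had 2 counts in the vehicle libraries and 110 in the YEXX-2A libraries (ratio 41.6, exact interval 11.2 to 348), and its call was lost without vehicle replicate 2 (adjusted p = 0.0662) and with the library score as a covariate. The thyrotropin receptor gene Tshr rose by 2.85 on the log2 scale, the interferon-inducible Gbp1 by 3.21 and Samd9 by 2.04. Sorbs2 rose by 2.20 and Mphosph8 by 2.00. The largest falls beside Fmod and Tagln were those of Col11a1 (-2.44), the angiotensin-converting enzyme gene Ace (-2.15), Rasgrf1 (-1.92) and Siglec10 (-1.91). Without YEXX-2A replicate 1 the count of called genes was 1459 in place of 4145, and without replicate 2 it was 1044. With only the vehicle and YEXX-2A libraries it was 1408, with the library score as a covariate 2328, and limma on FPKM put 62% of calls higher against 48.8% here.

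**Figure D2:**
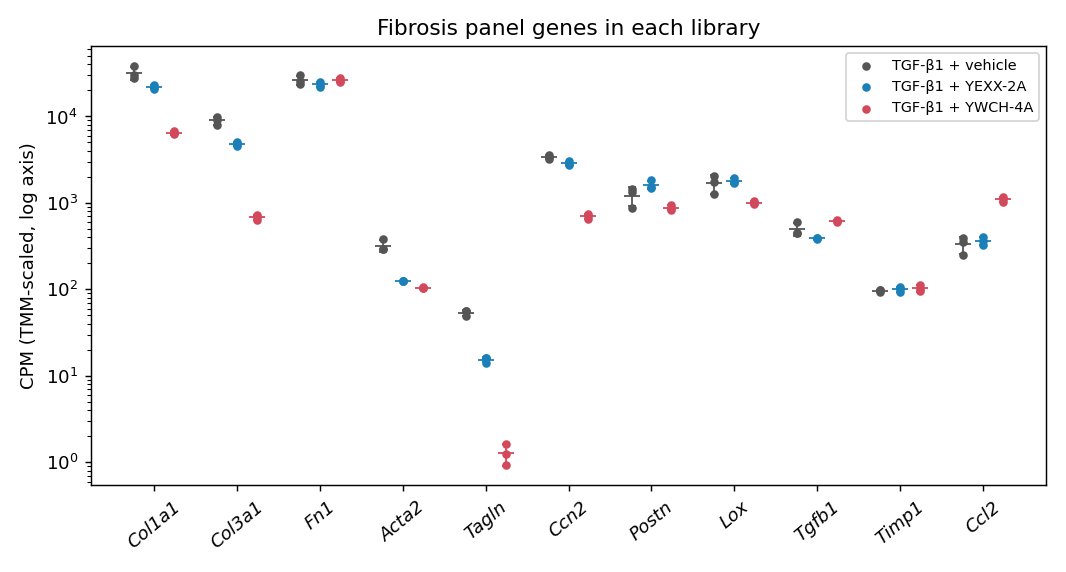
CPM of 11 panel genes on a log axis; each point is a library, and bars are the mean and SD of 3 libraries per group. Tagln was at 53.7, 15.4 and 1.28 CPM on average with vehicle, YEXX-2A and YWCH-4A, and Col3a1 at 8980, 4827 and 683 CPM.

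The second comparison asked the same of YWCH-4A. The collagen genes Col3a1 and Col1a1 and the contractile genes Tagln and Acta2 fell. Col3a1 went from 8980 ± 974 to 683 ± 46.9 CPM (SD, n = 3 each; log2 fold change -3.72, SE 0.10, edgeR adjusted p = 2.28e-09). Col1a1 went from 32190 ± 5510 to 6464 ± 306 CPM (log2 fold change -2.32, SE 0.12, edgeR adjusted p = 1.42e-07). Tagln fell by 5.37, Acta2 by 1.63 and Ccn2, a matricellular growth factor induced by TGF-β, by 2.28 on the log2 scale. Nos2, the inducible nitric oxide synthase, rose by 4.26 and the matrix metalloproteinase Mmp9 by 5.17. Of 11473 genes, 3516 were called, 1801 higher and 1715 lower, and 706 changed at least 2-fold.

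Among other panel genes, the sum of the pair of Col1a2 gene models went to 5915 ± 301 CPM (log2 fold change -2.38, SE 0.11, adjusted p = 8.49e-08). Hmox1 fell by 1.14, Lox by 0.75 and Smad3 by 0.43. Ccl2 rose by 1.72, Il6 by 0.87 and Tgfbr2 by 0.35. Postn (-0.46, adjusted p = 0.0479), Smad7 (0.31, adjusted p = 0.0188) and Tgfb1 (0.31, adjusted p = 0.0341) were called, with the Smad7 call lost without YWCH-4A replicate 2 (adjusted p = 0.0561) or 3 (0.0875). The Tgfb1 call held without vehicle replicate 2 and was lost without any other library (adjusted p 0.0524 to 0.112). The Postn call held without vehicle replicate 2 or YEXX-2A replicate 2 and was lost without any other library (adjusted p 0.0633 to 0.14). Fn1, the fibronectin gene, was at 26510 ± 3140 CPM with vehicle and 26150 ± 1360 with YWCH-4A (log2 fold change -0.02, SE 0.09, edgeR adjusted p = 0.889). Also not called were Timp1 (0.11), Mmp2 (-0.04) and Tgfbr1 (0.47). Of 26 TGF-β/SMAD targets, 7 rose and 10 fell (8 and 10 adjusted over the list alone), and camera did not call the list (adjusted p = 0.211).

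Cytokine, chemokine and NF-κB feedback genes rose in 31 of 33 cases with YWCH-4A and fell in 1 (31 and 1 adjusted over the list alone), with a median log2 fold change of 2.04. The neutrophil chemoattractant Cxcl1 rose by 3.95, the colony-stimulating factor Csf3 by 4.41 and Nfkbia, which encodes the NF-κB inhibitor IκBα, by 2.11. Camera called this list with both correlations (adjusted p = 1.14e-23, and adjusted p = 0.00075 with an estimated correlation). Matrix proteases and their inhibitors rose in 10 of 21 cases and fell in 5 (12 and 5 adjusted over the list alone; camera adjusted p = 0.0151, adjusted p = 0.12 with an estimated correlation). The collagenase Mmp13 rose by 5.47, Mmp10 by 3.89 and the stromelysin Mmp3 by 3.66, while the protease inhibitor Timp3 fell by 1.51. Summed over Ptprc, Tyrobp, Fcer1g, Lyz2 and C1qa, leukocyte transcripts stayed at or under 0.221 CPM in the YWCH-4A libraries and reached 0.19 CPM in a vehicle and 0.456 CPM in a YEXX-2A library.

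Of 36 collagens and matrix glycoproteins, 26 fell with YWCH-4A and 1 rose (27 and 1 adjusted over the list alone), Col12a1 by 1.83 and Sparc by 1.79 on the log2 scale. Camera called the list (adjusted p = 1.08e-15), with an adjusted p = 0.12 with an estimated correlation. Of 26 collagen-modifying genes, 19 fell and 2 rose (20 and 3 adjusted over the list alone), with Loxl2 at -1.53 and the transglutaminase Tgm2 at 1.93 (camera adjusted p = 4.05e-09, adjusted p = 0.196 with an estimated correlation). Contractile genes fell in 17 of 23 cases and rose in 3 (17 and 3 adjusted over the list alone), with the integrin Itga11 at -3.05 and the smooth muscle myosin gene Myh11 at 1.76. This list was called with both correlations (adjusted p = 3.36e-07, and adjusted p = 0.0296 with an estimated correlation). Canonical Wnt targets fell in 6 of 8 cases and rose in 1 (6 and 1 adjusted over the list alone), Apcdd1 by 1.92 and Axin2 by 0.89, with a camera adjusted p = 0.000371 and an adjusted p = 0.0879 with an estimated correlation. Tubulins, which fell with YEXX-2A, were lower in 6 of 9 cases and higher in 1 (median -0.34, camera adjusted p = 0.000917). That list was not called with an estimated correlation, nor by camera between the compounds (adjusted p = 0.743).

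With YWCH-4A, 27 of 32 ATF4 targets fell and 2 rose (28 and 2 adjusted over the list alone), with the glutathione-degrading enzyme gene Chac1 at -2.80, Trib3 at -2.64, the asparagine synthetase gene Asns at -1.25 and Atf4 itself at -1.15 (camera adjusted p = 2.15e-18, adjusted p = 0.12 with an estimated correlation). NRF2 antioxidant targets fell in 16 of 29 cases and rose in 2 (18 and 2 adjusted over the list alone). Nqo1, a quinone reductase, fell by 2.35 on the log2 scale, and Slc7a11, the cystine transporter, by 2.63. Cholesterol synthesis and SREBP2 target genes fell in 18 of 26 cases and rose in none (18 and 0 adjusted over the list alone), Hmgcs1 by 0.84, Fdps by 0.68 and Cyp51 by 0.59. The NRF2 and cholesterol lists were called with both correlations (adjusted p = 2.06e-07 and 2.06e-06, and adjusted p = 0.0136 and 0.016 with an estimated correlation). Hypoxia and glycolysis genes fell in 19 of 30 cases and rose in 3 (19 and 4 adjusted over the list alone; camera adjusted p = 3.74e-06, adjusted p = 0.0879 with an estimated correlation), with Pgk1 at -0.78 and the prolyl hydroxylase Egln3 at 2.04.

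Interferon-stimulated genes rose in 12 of 34 cases with YWCH-4A and fell in 4 (13 and 4 adjusted over the list alone), and camera did not call the list (adjusted p = 0.0958; 0.0464 with the library score as a covariate). Irf1 rose by 0.95 on the log2 scale, while Isg15 fell by 0.87. Ribosomal protein genes rose in 23 of 46 cases (29 adjusted over the list alone; camera adjusted p = 1.21e-06, adjusted p = 0.269 with an estimated correlation), and 1 of 13 mitochondrially encoded genes was lower (0 adjusted over the list alone; camera adjusted p = 0.327). Without vehicle replicate 2, 6 of the 13 were lower and the median was -0.21 in place of -0.11 (camera adjusted p = 0.00981), and with the library score as a covariate 8 were lower (median -0.21, camera adjusted p = 0.00517). Markers of other kidney cells were few among the tested genes. Of 6 kidney epithelial markers 1 rose and 2 fell (1 and 3 adjusted over the list alone; camera adjusted p = 0.0979), and with YEXX-2A 3 fell and none rose (4 and 0 adjusted over the list alone; camera adjusted p = 0.0604). Of 5 endothelial markers 2 rose and 2 fell with YWCH-4A (2 and 2 adjusted over the list alone; camera adjusted p = 0.661), and with YEXX-2A 2 rose (2 rose and 2 fell adjusted over the list alone; camera adjusted p = 0.622). Of 17 fibroblast and mesenchymal markers 3 rose and 5 fell with YWCH-4A (4 and 5 adjusted over the list alone; camera adjusted p = 0.152), and 1 rose and 6 fell with YEXX-2A (2 and 7 adjusted over the list alone; camera adjusted p = 0.161; 0.00661 with the library score as a covariate).

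Several of the largest changes with YWCH-4A were of genes near the floor in the other group. Cd6 had 3 counts with vehicle and 329 with YWCH-4A (ratio 80.8, exact interval 27.4 to 394), Gpr132 2 and 152 (ratio 56, interval 15.2 to 467), Dnah17 2 and 135 (ratio 49.7, interval 13.5 to 415) and Pla2g5 3 and 166 (ratio 40.8, interval 13.7 to 200). Col11a1 had 123 counts with vehicle and 2 with YWCH-4A (ratio 83.4, interval 22.6 to 697). Aoc3, an amine oxidase, fell by 4.62 on the log2 scale, Slc17a6 by 3.96, Actg2, another smooth muscle actin, by 3.94 and Wfdc1 by 3.90. Limma on FPKM put 78.1% of its calls higher, against 51.2% here, and its median over all tested genes was 0.18 in place of 0.03. That fit changed the kind of value and the test along with the scaling. Changing the scaling alone put 47.7% (DESeq2 factors) and 49.9% (upper-quartile factors) higher, with medians of 0.01 and 0.03. Directions of small changes thus depend on the processing. Leaving out a library gave 2450 to 4588 called genes, and with the library score as a covariate 5673 were called.

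**Figure D3:**
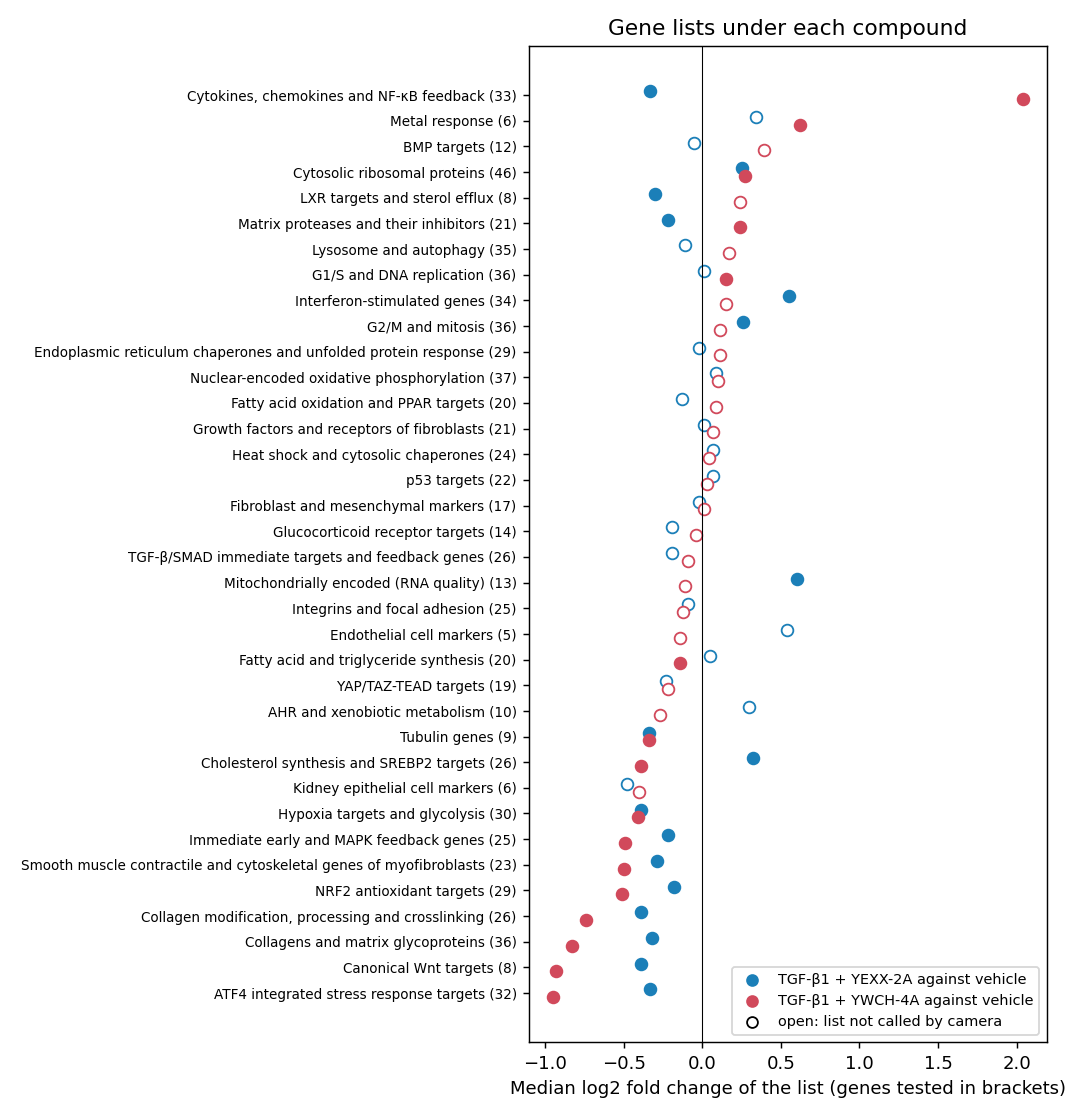
Median log2 fold change of each gene list, with the number of tested genes in brackets, for each compound against vehicle; filled points are lists called by camera with the preset correlation. The cytokine list lay at 2.04 with YWCH-4A and -0.33 with YEXX-2A, and the cholesterol list at -0.39 and 0.32.

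The compounds were also compared with each other. Cytokine and NF-κB genes were higher with YWCH-4A than with YEXX-2A in 32 of 33 cases and lower in 1 (32 and 1 adjusted over the list alone; camera adjusted p = 6.49e-27, adjusted p = 0.000515 with an estimated correlation), with Nos2 at 5.07 and Cxcl1 at 4.53 on the log2 scale. Cholesterol synthesis genes were lower in 21 of 26 cases and higher in none (21 and 0 adjusted over the list alone; camera adjusted p = 6.59e-12, adjusted p = 0.00349 with an estimated correlation), with Hmgcs1 at -1.59 and Cyp51 at -1.55. Interferon-stimulated genes were lower in 19 of 34 cases and higher in 6 (22 and 6 adjusted over the list alone; camera adjusted p = 0.000229, adjusted p = 0.128 with an estimated correlation). Isg15 was at -1.49 and Rsad2 at -1.59, whereas the transcription factor gene Irf1 was at 1.22. In all, 3593 genes were called, 1858 higher and 1735 lower with YWCH-4A, and 767 differed at least 2-fold.

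Of the fibrosis panel genes, Col3a1 was lower with YWCH-4A than with YEXX-2A (log2 fold change -2.82, SE 0.10, edgeR adjusted p = 1.29e-08), Col1a1 was at -1.76, the Col1a2 sum at -1.83, Ccn2 at -2.03, Tagln at -3.58, Postn at -0.87, Lox at -0.84 and Hmox1 at -0.68. Higher with YWCH-4A were Ccl2 (1.60), Tgfb1 (0.67), Il6 (0.66) and Tgfbr2 (0.36). For Acta2 the difference was -0.27 (SE 0.10, edgeR adjusted p = 0.0544), and for Smad3 -0.20 (SE 0.07, adjusted p = 0.0512), neither called. Also not called were Fn1 (0.15), Timp1 (0.04), Mmp2 (0.18), Smad7 (0.19) and Tgfbr1 (-0.44). TGF-β/SMAD targets were higher in 6 and lower in 7 of 26 cases (7 and 9 adjusted over the list alone; camera adjusted p = 0.599).

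Collagens and matrix glycoproteins were lower with YWCH-4A in 25 of 36 cases and higher in 4 (25 and 5 adjusted over the list alone; camera adjusted p = 4.25e-08, adjusted p = 0.262 with an estimated correlation). Matrix proteases and inhibitors were higher in 13 of 21 cases and lower in 5 (13 and 5 adjusted over the list alone; camera adjusted p = 0.00101, adjusted p = 0.061 with an estimated correlation), with Mmp13 at 6.59, Mmp9 at 5.32 and Mmp3 at 4.67. ATF4 targets were lower in 25 of 32 cases and higher in 2 (26 and 2 adjusted over the list alone; camera adjusted p = 1.09e-12, adjusted p = 0.175 with an estimated correlation). Mitochondrially encoded genes were lower in 11 of 13 cases (12 adjusted over the list alone; camera adjusted p = 1.85e-05, adjusted p = 0.369 with an estimated correlation). Hypoxia and glycolysis genes were higher in 6 and lower in 3 of 30 cases (6 and 3 adjusted over the list alone; camera adjusted p = 0.829).

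Of the largest differences, Csf3 was at 5.68 on the log2 scale, Slc7a11 at -3.45, Aoc3 at -4.32, Slc17a6 at -4.20, the proteoglycan gene Epyc at -3.53 and Wfdc1 at -3.39. Dnah17 had no count in the YEXX-2A libraries and 135 with YWCH-4A. Its ratio was 43.9 with 3 counts assumed for the YEXX-2A group, a point value without an interval. L1cam had 3 and 189 counts (ratio 61.4, exact interval 20.7 to 301), and Pla2g5 3 and 166 (ratio 54, interval 18.1 to 264). Cd6, at 0.119 ± 0.112 CPM with YEXX-2A and 5.79 ± 0.303 CPM with YWCH-4A, differed by 5.63. Without vehicle replicate 2 the count of called genes was 6001 in place of 3593, and with only the libraries of the compounds it was 5903. It was 2225 without YEXX-2A replicate 2, 2288 without YWCH-4A replicate 1 and 2293 without YWCH-4A replicate 3, and limma on FPKM put 72.6% of calls higher against 51.7% here.

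Against vehicle, 1512 genes were called in the same direction with both compounds, 634 higher and 878 lower. Among these were the falls of Col1a1, Col3a1, Acta2, Tagln, Fmod, Pgk1 and Ldha and the rise of Tshr. Independent lists of these sizes would share 317 genes in each direction. In 50 simulations all 9 libraries were redrawn gene by gene from the mean vehicle profile, with no group changed and shared vehicle libraries. There 0.08 genes on average and 1 at most were called in both. Unchanged groups leave few calls to share, so this count is no baseline for the overlap of real responses. The simulations also lacked the shift of many genes together in vehicle replicate 2, and may understate what shared controls give. A further 239 genes were called in opposite directions, 160 of them lower with YEXX-2A and higher with YWCH-4A, where independent lists would share 636. All 239 were called between the compounds, as were 388 of the 1512. The covariance of the log2 fold changes across genes was 0.126, against 0.04 in the simulations, a difference of 0.086. Their correlation across genes, which are not independent replicates, was 0.39, below the 0.579 of the simulations. Both comparisons used the same 3 vehicle libraries, which are too few to split, so part of the excess may come from these shared controls. The shared count was 704 without YEXX-2A replicate 1, 570 without YEXX-2A replicate 2, 924 without YWCH-4A replicate 1, 908 without YWCH-4A replicate 2, and 642 when each comparison used only its own groups.

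**Figure D4:**
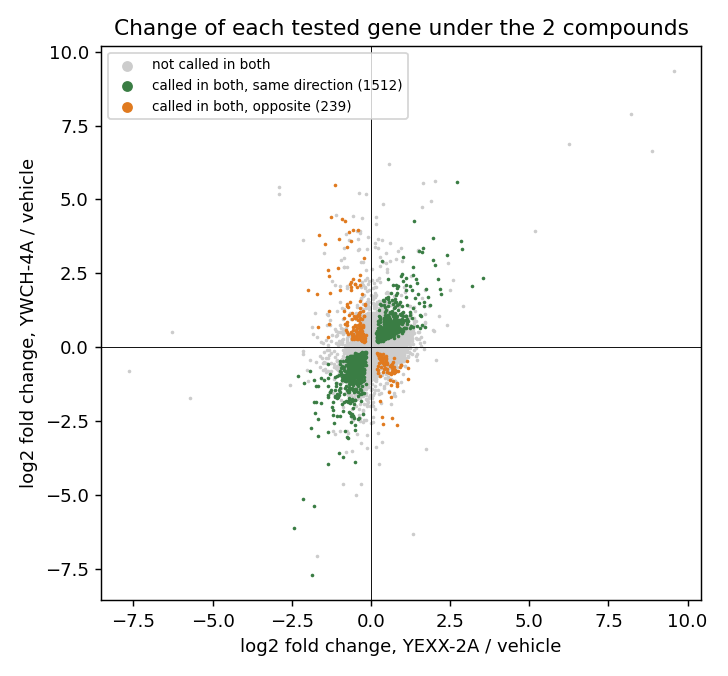
Log2 fold change against vehicle of each of the 11473 tested genes with YEXX-2A (x axis) and YWCH-4A (y axis); points are genes, coloured by whether they were called with both compounds. The plot holds 1512 genes called in the same direction and 239 called in opposite directions.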

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

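The test for leukocyte transcripts was set up after the result it bears on was seen, and the library score covariate and the thinning of counts were added after the data were examined. The groups have 3 libraries each, so no library was tested as an outlier. The results given here are those whose change against vehicle differed between the compounds in the direct edgeR or camera test, with opposite calls for each compound. Tgfb1 was lower with YEXX-2A (-0.37) and higher with YWCH-4A (0.31), a difference of 0.67 on the log2 scale. Vehicle replicates 1 to 3 were at 454.8, 598.8 and 454.2 CPM, so replicate 2 enlarged the fall and reduced the rise. Each call of Tgfb1 against vehicle was lost without YEXX-2A replicate 1 (adjusted p 0.0615 with YEXX-2A and 0.0555 with YWCH-4A) or replicate 2 (0.0753 and 0.0601), that with YWCH-4A also without any other library but vehicle replicate 2 (0.0524 to 0.112), and the call between the compounds was kept in each of the 20 alternatives that set no minimum fold. The list of matrix proteases and their inhibitors had a median of -0.22 with YEXX-2A and 0.24 with YWCH-4A, and of 0.48 between the compounds. Its call with YEXX-2A (adjusted p = 0.0282) was lost without vehicle replicate 3 (0.0508) and with the library score as a covariate (0.087), and with an estimated correlation its adjusted p was 0.229, 0.12 and 0.061 in the 3 comparisons. The list of cytokines, chemokines and NF-κB feedback genes had medians of -0.33 and 2.04, and of 2.08 between the compounds, with an adjusted p of 0.136, 0.00075 and 0.000515 with an estimated correlation. The list of cholesterol synthesis and SREBP2 targets had medians of 0.32 and -0.39, and of -0.62 between the compounds.

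Vehicle replicate 2 set the main axis of within-group variation (41.1% of it). Differences in log2 CPM were correlated across 7096 genes, which are not independent replicates. YEXX-2A less vehicle replicates 1 and 3 stood at -0.63 with vehicle replicate 2 less replicates 1 and 3, with these 2 libraries shared. It stood at -0.34 with YWCH-4A replicate 3 less replicates 1 and 2, with no library shared. With each library's score on the main axis as a covariate, the called YEXX-2A changes had a median of 0.56 of their size (0.49 to 0.74 with a library left out). What part of the 4145 calls comes from the axis thus cannot be told apart from the compound. Fits with a library left out kept the scores from all 9 libraries, so they do not test how far a single library set the axis. By the same median of ratios per gene the interferon list kept 0.79 (0.7 to 0.91 with a library left out), and its median kept 0.93 (0.8 to 1.1), which argues against the axis as its whole source. Thinning all libraries to a common depth left 3904 calls, which argues against unequal counting depth alone. In each group the library with the smallest total had the highest score on the axis. These were vehicle replicate 2 (51.3), YEXX-2A replicate 3 (-5.6) and YWCH-4A replicate 3 (6). Thinning cannot test a difference in quality or composition that goes with library yield. A response to YEXX-2A and a difference in culture or RNA quality may both contribute, and GC content was not tested here.

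The opposite movement of cholesterol synthesis genes was weighed against the same axis. With the score as a covariate the list kept 0.96 of its median under YEXX-2A (0.88 to 1.1 with a library left out and the scores unchanged). The median of ratios per gene was 0.74 (0.65 without YEXX-2A replicate 3). Both argue against the axis as its whole source. The list was also called with YWCH-4A and between the compounds with an estimated correlation (adjusted p = 0.016 and 0.00349), though not with YEXX-2A (adjusted p = 0.0739). A hypothesis is that the compounds may act in opposite directions on sterol synthesis, and sterol content or serum lipids were not measured here.

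The joint rise of cytokine genes and fall of collagen genes with YWCH-4A was weighed against other cells and against composition. The 5 leukocyte markers summed to at most 0.221 CPM in a YWCH-4A library, which argues against leukocytes in the cultures. This outcome could be foreseen in an established fibroblast line whose macrophage and leukocyte list had under 5 tested genes, so the check adds little. With plain library sizes the median of all genes moved by 0.219 (0.199 to 0.234 across the YWCH-4A libraries) and that of the cytokine list by 2.24, which argues against the loss of collagen counts as the source of the rise. GC content was not tested and a response of the fibroblasts to YWCH-4A, or to something given with it, stays open.

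The 6 libraries of each comparison can be split in 10 ways, the real one included, too few for a share under 0.05. For YEXX-2A against vehicle 1 of 10 splits, the real one, gave 4145 or more genes (highest other 1) and 1 of 10 gave 17 or more lists (highest other 11). For YWCH-4A against vehicle 1 of 10 gave 3516 or more genes (highest other 0) and 1 of 10 gave 16 or more lists (highest other 15). For YWCH-4A against YEXX-2A 1 of 10 gave 3593 or more genes (highest other 0) and 1 of 10 gave 16 or more lists (highest other 13). Every other split mixed the 2 groups, which puts their difference into the spread, so few gene calls were built in. For YWCH-4A against vehicle the mixed splits still called 4 to 15 lists. Camera with the preset correlation thus also calls lists under mixed groupings. Of 100 assignments of the 9 libraries to groups, 2 gave 1512 or more genes called the same way against the reference, the real one included. The other (1805) kept the 3 groups whole and took the YWCH-4A libraries as the reference. A draw with that reference and with vehicle and YEXX-2A libraries mixed gave 1111. Nearly all other draws mixed the groups and called no gene in both. The draws thus show that the groups differ, and cannot tell whether the compounds share a response.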

How the results depend on the processing

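The library score covariate and the thinned counts were chosen after seeing the data. For YEXX-2A against vehicle the count of called genes was 1408 with only the 2 groups compared, 1931 with the replicate block, 2328 with the score covariate (1991 shared with the 4145) and 285 at 2-fold. For YWCH-4A against vehicle it was 5673 with the covariate and 706 at 2-fold, and between the compounds 5903 with only the 2 groups compared and 767 at 2-fold. Genes called the same way with both compounds numbered 642 with only the 2 groups compared in each comparison, 812 with the block and 89 at 2-fold. Leaving out a library gave 1044 (without YEXX-2A replicate 2) to 5308 (without vehicle replicate 3), 2450 to 4588, 2225 (without YEXX-2A replicate 2) to 6001 (without vehicle replicate 2), and 570 to 2108. Fewer libraries, or a changed share of the spread from vehicle replicate 2, enter some of these fits, and the cause was not tested otherwise. With only the 2 groups compared, the fit for YEXX-2A against vehicle (1408) lacked the YWCH-4A libraries, which varied least. That between the compounds (5903) lacked vehicle replicate 2. Counts with DESeq2 factors, upper-quartile factors, no or a stricter filter, DESeq2, limma and thinning stayed within 1.5 times.

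With an estimated correlation camera called 0, 4 and 2 lists (7, 11 and 8 at an unadjusted p under 0.05), and fry 28, 30 and 26. Under the covariate, Lox and Ccl2 with YEXX-2A were at -0.24 and -0.22 in place of 0.09 and 0.13. Stability was counted for the called genes of the panel, the largest changes and the leading genes of lists and pathways. Not all of these are named in the text. For YEXX-2A, 121 of 150 kept their call in all of the 20 alternatives without a minimum fold that tested them. The counts were 152 of 159 for YWCH-4A and 132 of 134 between the compounds. Genes that a filter removed were not counted as lost. Among these under the stricter filter were Cd6, Dnah17 and Pla2g5, with under 1 CPM in the vehicle and YEXX-2A libraries. Col11a1, at means of 0.57 and 0.0381 CPM with YEXX-2A and YWCH-4A, was another. Same-numbered replicates did not deviate together (correlations from -0.265 to 0.081, and 0 libraries closest to their own number), which gave no sign of pairing. With 3 libraries per group a modest shared effect could go unseen, so pairing is not excluded. The replicate block gave 2787 and 2612 genes in the other comparisons. Genes with few counts, such as Rbp4, are limited by depth.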

Other observations

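The pathways and genes described here were chosen after their values were seen, from all 314 pathway terms of the deposited annotation with at least 10 tested genes, by a Fisher's exact test of called genes adjusted over pathways and directions. With YWCH-4A, antigen processing and presentation genes were higher in 35 of 64 cases (54.7% against 18.3% of 4949 annotated genes, adjusted p = 8.55e-09). Cd74, the invariant chain of class II molecules, rose by 1.99 on the log2 scale and the RT1 genes RT1-Da and RT1-S3 by 1.15 and 0.70, with reads that can be split between RT1 copies. Complement and coagulation genes were higher in 15 of 30 cases (adjusted p = 0.00129), with C3 at 2.35, Clu at 1.34, C1s at 1.15 and Plat, the tissue plasminogen activator, at 1.06. Proteasome genes were higher in 16 of 44 cases (adjusted p = 0.0253), led by the immunoproteasome subunits Psmb9 (1.01) and Psmb10 (0.78), with Psmb8 at 0.47 and the activator subunit Psme2 at 0.78. Axon guidance genes were lower in 40 of 133 cases (adjusted p = 0.00134), among them Sema3a (-2.54), Wnt4 (-2.19), Fyn (-1.18) and Pak1 (-0.91). Genes of a pathway are not independent of each other, which this test does not allow for.

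With YEXX-2A, protein export genes were higher in 11 of 21 cases (52.4% against 18.7%, adjusted p = 0.0206). The signal peptidase subunits Spcs2, Sec11c and Spcs1 rose by 0.49, 0.46 and 0.39, and Srp14, a part of the signal recognition particle, by 0.43. The calls of Spcs1, Srp14 and Sec11c were lost without YEXX-2A replicate 2. RNA transport genes were higher in 44 of 152 cases (adjusted p = 0.034), with Ranbp2, a nuclear pore protein, at 0.73 and the elongation factor gene Eef1a1, which has near-identical copies, at 0.41.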
